A study of Mus musculus with 6 samples.

How the data were processed

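Palate RNA samples were compared, 3 from Fz1-/-;Fz2+/+ embryos and 3 from Fz1-/-;Fz2-/- embryos at embryonic day 13.5, called Fz1-null and double-null samples here. Per the labels, palates came from embryos of a mixed background and of mixed gender, total RNA was extracted with Trizol and RNeasy columns and labelled with biotin, and each sample was hybridised to an Affymetrix Mouse430_2 array. The labels give no embryo, litter or pool for any sample, so p-values measure the spread between these samples, which may in part be technical.

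The value table was deposited as log2 probe set values made by the authors with RMA (background correction, quantile normalisation across arrays and median polish over the probes of a set), per the submitters' processing notes. The RMA version and software are not given in the sources used here. The values ran from 2.83 to 14.7, and the array medians ran from 7.22 to 7.27. RMA gives no call of presence or absence, so a dim probe set was not called absent. Quantile normalisation gives every array nearly the same distribution of values, so a shift shared by most transcripts would not be seen.

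A table of the authors' own comparison was also deposited, with a log2 fold change, a signed linear fold change and an unadjusted p-value for each probe set, per the file headers. Its log2 fold change equalled the difference of group means of the value table with the sign turned (largest difference 4.93e-08), so there a positive value means higher in the Fz1-null samples. All differences below are double-null minus Fz1-null, the opposite direction. The test behind the deposited p-values is not named in the file headers. For 43184 of 45037 probe sets the deposited p-value equalled an unpaired equal-variance test of 3 against 3 arrays, for 1852 the unequal-variance version, and for 1 neither, at a tolerance of 1e-06. Cells outside the named columns of that table were not used.

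Of 45101 probe sets, 64 Affymetrix controls were left out and 45037 were tested. Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq annotation of assembly GRCm38.p6. A single gene symbol was given for 34945 probe sets, several for 932, and 9160 were not listed and are unnamed here. By Entrez identifier, 34741 of the single-symbol probe sets matched RefSeq. The array files carry no coordinates, so RefSeq served only for names and for which genes neighbour each other.

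The main comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default moderation) on the deposited log2 values of all 6 arrays, with genotype as the only term. Benjamini-Hochberg adjustment ran over the 45037 probe sets, with a two-sided adjusted p threshold of 0.05. Standard errors (SE) are limma's moderated ones, and SD is that of the 3 arrays of a group. With 3 arrays against 3, an exact permutation test of a single value cannot give a p below 0.1, so only the moderated model was used. Replicate numbers 1 to 3 occur in both groups in the labels, which do not say what a number shares. Deviations from the group means correlated at 0.63, 0.44 and 0.63 between the arrays numbered 1, 2 and 3, each above 0.1, so the numbers were taken as pairs from the data, and the fit with the replicate number as a block was computed beside the main one. No other batch is given in the labels.

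Gene lists were tested on 18194 genes, each by its single-symbol probe set with the highest mean, with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists. A further list, of sex-linked genes, had fewer than 5 measured members and was not tested. The 29 lists held 501 genes, of which 471 were measured. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone.

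The sample groups, the main test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Fzd1 and Fzd2, then up to 10 genes in each direction past the threshold without overlap between groups, filled to 10 by the smallest p, and then up to 3 members of each list with the smallest p. The alternatives were the probe sets above the median of mean values, eBayes with an intensity trend or robust, the replicate block, repeated quantile normalisation, centring on array medians, array weights, log2 of the value plus 32, leaving out each array, 1 probe set per gene, the mean of a gene's probe sets, an adjusted p threshold of 0.1, and an added requirement of a 1.5-fold difference. Added after the data were seen were the deposited p-values with Benjamini-Hochberg adjustment, the replicate block with an estimated correlation or fry, the block without each pair of arrays, the Wnt receptor list without Fzd1 and Fzd2, and the osteogenic list without Ibsp.

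The fits were tested on simulated arrays with the means and pair differences of these probe sets, of which 200 were changed, 50 at each fold. Noise was normal, with variances drawn from the distribution that limma fitted over all probe sets. The simulated arrays thus follow limma's own model, so real arrays may give poorer rates. At an adjusted p of 0.05 the fit without the block recovered 20% of probe sets changed 1.5-fold, 84% at 2-fold and 98% at both 3-fold and 4-fold, with 0 false calls. The blocked fit recovered 86% at 1.5-fold and 100% at each larger fold, with 9 false calls. Camera called 0 of 28 lists on unchanged simulated arrays and recovered an endothelial list shifted by 0.3 on the log2 scale. The simulated noise was drawn for each gene alone, so genes did not move together as they can on real arrays. The shift was also larger than the mean difference of every called list but the osteogenic one. These results therefore do not show how often camera miscalls lists on the real arrays.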

Results

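Transcript abundance was measured in microdissected mouse palates at E13.5, when the palatal shelves are growing and have not yet fused. Frizzled 1 and Frizzled 2, encoded by Fzd1 and Fzd2, are receptors for Wnt ligands. All 6 samples lacked Fzd1 by genotype, and the question was which transcripts differed when Fzd2 was lost as well, so no wild-type palate was part of the comparison. There were 3 Fz1-null arrays (Fz1-/-;Fz2+/+) and 3 double-null arrays (Fz1-/-;Fz2-/-), numbered 1 to 3 in each group. The number of arrays limits the precision. Over the 45037 probe sets, arrays with the same number correlated at 0.997 in each of the 3 pairs, and arrays of the same group at 0.991 to 0.994, so arrays of 1 number were closer to each other than to arrays of their own genotype.

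Fzd2 was lower in the double-null palates in each of the 3 pairs and by each of its 3 probe sets. Its brightest probe set lay at a log2 value of 11.57 ± 0.10 (SD, n = 3) in Fz1-null and 10.31 ± 0.19 (SD, n = 3) in double-null palates, a log2 difference of -1.25 (SE 0.11), or 2.38-fold lower. The other probe sets differed by -1.36 (SE 0.14, 2.57-fold lower) and -1.48 (SE 0.21, 2.78-fold lower). With limma and adjustment over all probe sets, none of them passed without the block (adjusted p = 0.217, 0.353 and 1.00), and all 3 passed with the replicate block (adjusted p = 0.00889, 0.00816 and 0.00615 in the same order). Adjusted over the 5 Fzd1 and Fzd2 probe sets alone, the 3 Fzd2 probe sets gave adjusted p of 2.4e-05, 3.9e-05 and 0.00023 without the block. In double-null palates the brightest probe set read 42.0% of its Fz1-null level. Which part of Fzd2 is deleted and where the probes lie are not known here, so this share does not measure remaining intact transcript.

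Fzd1, null in both groups, had a probe set near the bottom of the scale and another near the middle. The dimmer probe set read 4.39 ± 0.16 (SD, n = 3) in Fz1-null and 4.35 ± 0.07 (SD, n = 3) in double-null palates. The brighter probe set read 7.39 ± 0.02 and 7.47 ± 0.04 (SD, n = 3 each), a log2 difference of 0.08 (SE 0.07), higher in 3 of 3 pairs without overlap between the groups. Neither passed the threshold (adjusted p = 1.00 for both over all probe sets, and 0.703 and 0.331 adjusted over the 5 probe sets alone). The dimmer one differed by -0.04 (SE 0.10), and by 0.03 without Fz1-null array 2. Without wild-type arrays, and with the deleted part not known here, these probe sets do not check the Fzd1 genotype.

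**Figure D1:**
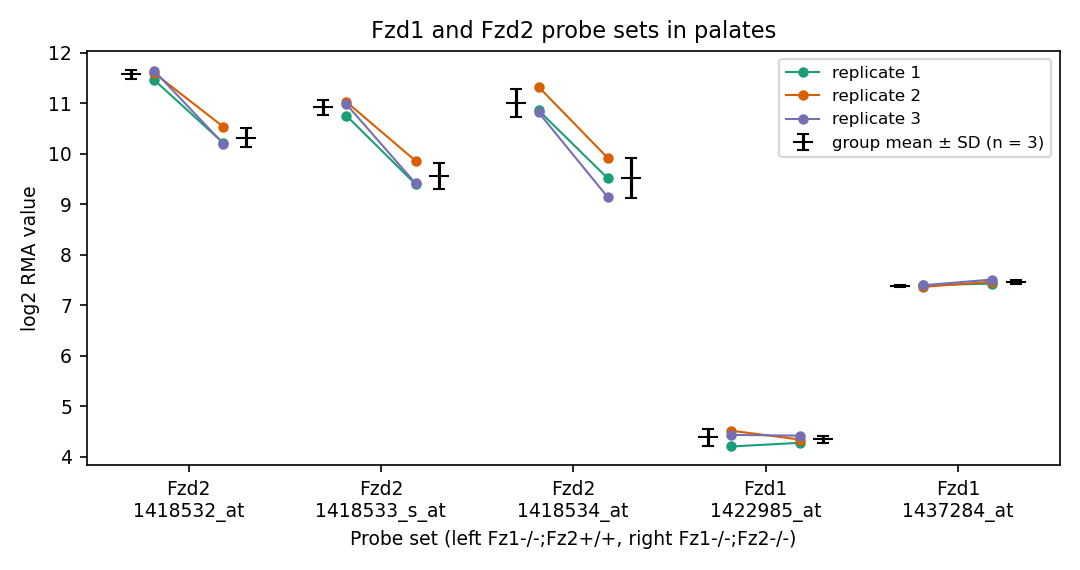
Log2 RMA values of the 3 Fzd2 and 2 Fzd1 probe sets on each array (points, lines joining arrays of the same replicate number), with Fz1-/-;Fz2+/+ on the left and Fz1-/-;Fz2-/- on the right of each probe set, and group means ± SD (n = 3) in black. Each Fzd2 line falls, by 1.06 to 1.68 on the log2 scale, and the Fzd1 values stay near 4.4 and 7.4.

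Outside Fzd2, no transcript passed the test. With limma without the block, 0 of 45037 probe sets passed an adjusted p of 0.05, 431 (311 higher and 120 lower in double-null palates) lay at an unadjusted p under 0.05, which is 0.957% against 5% by chance, and the deposited p-values gave 0 after Benjamini-Hochberg adjustment. With the replicate block 3 probe sets passed, all of Fzd2 and all lower (93 with the pair numbered 1 left out, 46 higher and 47 lower, and the 3 of Fzd2 with either other pair left out), and 2121 (4.71%) lay at an unadjusted p under 0.05. The 3 double-null arrays lay all above or all below the 3 Fz1-null arrays for 2032 probe sets, 4.51% against 10% by chance. Both chance shares assume 6 exchangeable arrays, and arrays of the same number were closer than that. At least 2-fold lower in all 3 pairs were 3 probe sets, again those of Fzd2, and 0 were at least 2-fold higher in all 3.

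By mean difference, 8 probe sets reached 2-fold, 7 lower and 1 higher in double-null palates. Beyond Fzd2, the lower ones were 2 of Xist, the non-coding RNA of X inactivation, 1 of Ibsp, a bone matrix sialoprotein, and 1 without a gene name, and the higher one was of Hoxa5, a homeobox gene. These genes were named after their values were seen. Ibsp differed by -2.01 (SE 1.04) on the log2 scale, with pair differences of -1.20, -4.46 and -0.37, and by -0.92 (SE 0.53) in its other probe set. Hoxa5 differed by 1.02 (SE 0.76), with pair differences of 0.20, -0.07 and 2.92, and by 0.07 (SE 0.10) in its other probe set. Xist differed in its most different probe set by -2.16 (SE 1.77), with pair differences of 1.22, -7.66 and -0.04, and the sexes were not evenly mixed over the arrays, as described below. Each had an adjusted p of 1.00 without the block and 0.966 with it.

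None of the 10 genes with the smallest p on the higher side passed the threshold, and they were named by p alone, each by its probe set with the smallest p. Zic1 and Zic5, zinc finger genes of the dorsal neural tube, had log2 differences of 0.75 (SE 0.17) and 0.57 (SE 0.13). Sox1, a neural progenitor gene, differed by 0.34 (SE 0.09), and Pou3f1, a POU factor, by 0.36 (SE 0.10). Vtn, the adhesion glycoprotein vitronectin, went from 8.23 ± 0.17 to 8.89 ± 0.23 (SD, n = 3 each), a difference of 0.65 (SE 0.14). The others were Iglv1 (0.34), Arrdc5 (0.31), Dnajc1 (0.30), Mep1b (0.28) and Nptx1 (0.25). Arrdc5 (4.58 in Fz1-null and 4.89 in double-null palates), Dnajc1 (4.19 and 4.49) and Mep1b (4.37 and 4.64) read near the floor. That limits what their differences can show. Of all probe sets of a gene, 2 of 3 were higher for Iglv1 and 3 of 6 for Dnajc1, and all were for the other 8. The named probe sets of all 10 were higher in 3 of 3 pairs with no overlap between the groups (adjusted p = 1.00 for each, and 0.20 for Zic5 and 0.966 for the other 9 with the replicate block).

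On the lower side Fzd2 came first. Gm11627, a predicted gene that neighbours Fzd2 in RefSeq, went from 7.65 ± 0.06 to 7.11 ± 0.05 (SD, n = 3 each), a log2 difference of -0.54 (SE 0.07), and Mtrex, a helicase of nuclear RNA decay, differed by -0.79 (SE 0.17). Rspo1, which encodes a secreted protein that strengthens Wnt signalling, differed by -0.32 (SE 0.08), the circadian factor Arntl2 by -0.43 (SE 0.12), and the transcription factor Zfhx3 by -0.30 (SE 0.09). The remaining members were Rnf128 (-0.29), Acpp (-0.27), Rhpn2 (-0.27) and Chdh (-0.26). Of all probe sets of a gene, 2 of 3 were lower for Mtrex and Acpp and 1 of 2 for Arntl2, and all were for the others. The named probe sets were all lower in 3 of 3 pairs without overlap. On both sides, choosing genes by smallest p favours such agreement, so it is no separate evidence. Apart from Fzd2, none passed (adjusted p = 1.00 for each of these 9 without the block; with it, 0.20 for Gm11627 and Mtrex and 0.966 for the other 7).

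**Figure D2:**
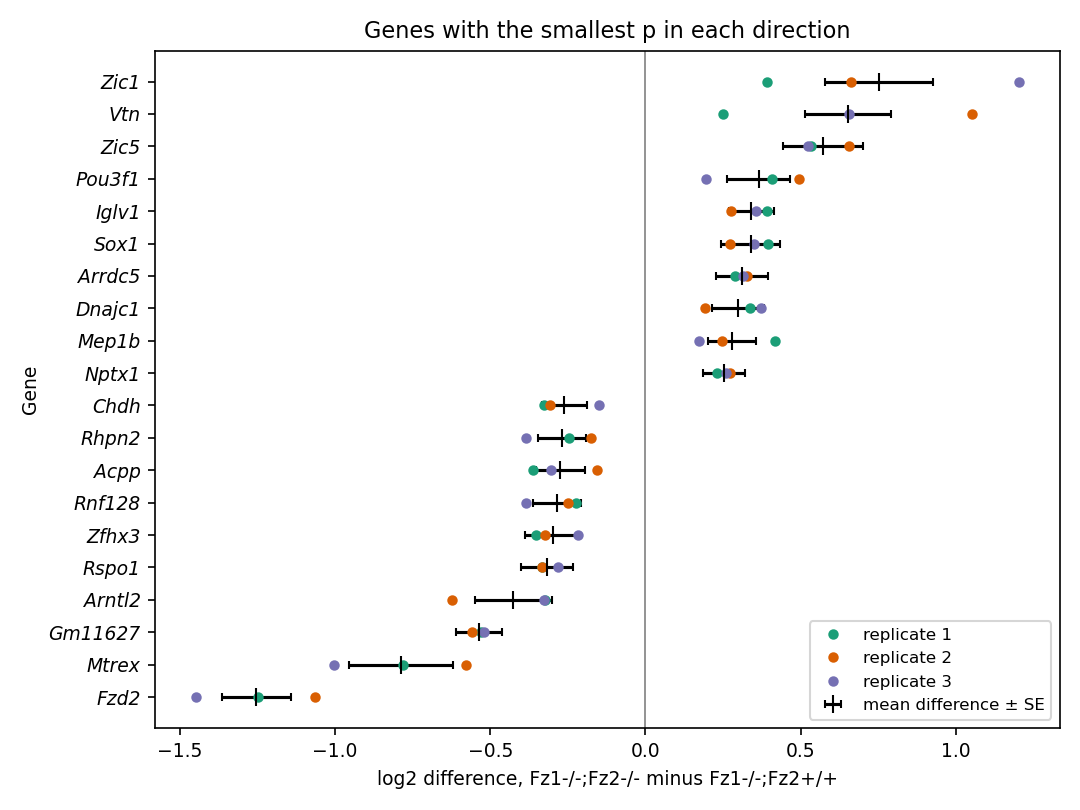
Log2 difference (double-null minus Fz1-null, horizontal axis) of the 10 genes with the smallest p in each direction (vertical axis), with black ticks and bars for the mean ± SE of the fit without the block and a coloured point for each pair of same-numbered arrays. Zic1 reaches 0.75 at the higher end, Fzd2 -1.25 at the lower end, and the 3 points of each gene lie on 1 side of 0, which choosing by smallest p favours.

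Among Wnt receptors and co-receptors, Fzd2 stood alone: 11 of 22 measured members were higher and 11 lower, with a mean log2 difference of -0.07 that became -0.02 without Fzd1 and Fzd2. The list did not pass camera (adjusted p = 0.196, and 0.594 without Fzd1 and Fzd2), but did so without double-null array 2 (mean -0.12, adjusted p = 0.0490) and by the mean of all probe sets of a gene (-0.09, 0.0264). Its mean shrank to -0.03 without double-null array 3 (camera adjusted p = 0.986) and to -0.05 without Fz1-null array 2 (0.433). Fzd2 was the 1 member past the threshold adjusted over the list alone, with or without the block. Rnf43, a ubiquitin ligase that removes Frizzled receptors, differed by -0.19 (SE 0.12). Of the Wnt and R-spondin ligands 12 of 23 were higher, with a mean of -0.01, a median of 0.01 and an upward camera direction (adjusted p = 0.968). Rspo1 was the 1 member past the threshold adjusted over the list alone, and only with the replicate block (adjusted p = 0.024 against 0.127 without it). Wnt1 differed by 0.17 (SE 0.11) and Wnt8a by -0.12 (SE 0.07).

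Target genes of Wnt/beta-catenin signalling and secreted Wnt antagonists did not pass camera (adjusted p = 0.397 and 0.196), though the antagonists passed among probe sets above the median value (mean -0.13, adjusted p = 0.0341) and by the mean of all probe sets of a gene (-0.09, 0.0373). Of the targets 10 of 17 were lower, with a mean log2 difference of -0.05, and of the antagonists 7 of 13, with a mean of -0.08. Without Fz1-null array 3 these means were -0.004 and -0.04, and without Fz1-null array 1 they were -0.07 and -0.11. The members with the smallest p were Wif1, a secreted inhibitor in both lists (-0.43, SE 0.20), the targets Rnf43 (-0.19, SE 0.12) and Nkd2, a negative regulator (0.14, SE 0.09), Sostdc1 (-0.37, SE 0.17) and Sost (0.22, SE 0.08), the last 2 being secreted antagonists. No member of either list passed the threshold over all probe sets or over the list alone.

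Planar cell polarity genes, which orient cells within a tissue and use Frizzled receptors, fell as a group by the preset-correlation test. Of 24 measured members 18 were lower, with a mean log2 difference of -0.06 (camera adjusted p = 0.0321; adjusted p = 0.695 with an estimated correlation) and pair means of -0.05, -0.03 and -0.09. The members with the smallest p were Wnt5a (-0.35, SE 0.26), Dvl3, a cytoplasmic transducer of Wnt signals (-0.15, SE 0.08), and the formin Daam2 (-0.12, SE 0.09), and no member passed alone. The call ended without double-null array 3 (mean -0.02, adjusted p = 0.475), Fz1-null array 1 (-0.05, 0.119) or Fz1-null array 2 (-0.05, 0.10). It also ended among probe sets above the median value (-0.06, 0.105), with array weights (-0.04, 0.0851) and with repeated quantile normalisation (-0.03, 0.148). In the pair numbered 3, where the list fell most, skeletal muscle genes had a mean of 0.60 and epithelial markers of -0.37.

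Palatal shelf transcription factors were lower in 20 of 24 members, with a mean log2 difference of -0.08 (camera adjusted p = 0.0262; adjusted p = 0.695 with an estimated correlation). Shox2 (-0.28, SE 0.14) and Msx1 (-0.37, SE 0.19), homeobox genes of the anterior palate, and Prrx2 (-0.22, SE 0.08) lay lower, and Meox2, a posterior palate gene, lay higher (0.31, SE 0.14). Anterior palate markers were lower in 5 of 6 members, Fgf10 among them (-0.15, SE 0.14), with a mean of -0.14 (adjusted p = 0.0336; 0.695 with an estimated correlation). Posterior markers did not pass: 5 of 6 were lower, among them Efnb1 (-0.06, SE 0.09, and 0.005 without double-null array 3) and Fgfr2 (-0.09, SE 0.08), with a median of -0.05 and a mean near 0 that Meox2 raised (adjusted p = 0.849). Without double-null array 3 the transcription factors had a mean of 0.03 (adjusted p = 0.515) and the anterior markers -0.08 (0.395), and their pair means were 0.05, -0.05 and -0.25, and 0.01, -0.14 and -0.29. In the pair numbered 3 skeletal muscle genes had a mean of 0.60 and epithelial markers of -0.37. The first call also ended without Fz1-null array 2 (-0.04, 0.215), and the second without double-null array 2 (-0.12, 0.150), Fz1-null array 1 (-0.13, 0.0896) or Fz1-null array 3 (-0.13, 0.132). Both ended among probe sets above the median value (-0.09, 0.105 and -0.14, 0.123) and with array weights (-0.05, 0.140 and -0.12, 0.0839), and the second with repeated quantile normalisation (-0.12, 0.0671). The transcription factors had a mean of -0.14 without double-null array 1 or 2, and the anterior markers -0.22 without double-null array 1.

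Of the other signalling lists, Hedgehog pathway genes were lower in 10 of 13 members with a mean of -0.06 (camera adjusted p = 0.0363; 0.695 with an estimated correlation, and 0.0608 with the replicate block). They included the Gli2 (-0.13, SE 0.11) and Gli3 (-0.13, SE 0.10) transcription factors and the co-receptor Cdon (-0.16, SE 0.08). Pair means were 0.04, -0.03 and -0.18, and in the third of these pairs skeletal muscle genes lay at 0.60 and epithelial markers at -0.37. The mean was 0.03 without double-null array 3 (adjusted p = 0.898), and the call ended without Fz1-null array 1 (-0.05, 0.0794), 2 (-0.04, 0.121) or 3 (-0.08, 0.0821), among probe sets above the median value (-0.06, 0.123), with array weights (-0.03, 0.167) and with repeated quantile normalisation (-0.03, 0.148). The mean was -0.11 without double-null array 1 and -0.09 without double-null array 2. BMP and TGF-beta pathway genes were lower in 14 of 24 members (adjusted p = 0.730), with Bmp5 at 0.15 (SE 0.16), the antagonist Chrd at 0.12 (SE 0.11) and Bambi at -0.10 (SE 0.12), and 0.01 without double-null array 3. FGF pathway genes were lower in 12 of 18 (adjusted p = 0.463), with the FGF-responsive factor Etv5 at -0.14 (SE 0.11), Fgf10 at -0.15 (SE 0.14) and Fgfr2 at -0.09 (SE 0.08).

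Cell cycle genes were lower in 27 of 30 members by a mean of -0.04 (camera adjusted p = 0.0321; 0.695 with an estimated correlation), with the replication factor Mcm4 at -0.11 (SE 0.09), the mitotic kinase Aurkb at -0.08 (SE 0.07) and Tyms at -0.13 (SE 0.13). Pair means were 0.03, 0.02 and -0.17, with 7, 11 and 29 of 30 lower, and in the pair numbered 3 skeletal muscle genes lay at 0.60 and epithelial markers at -0.37. Without double-null array 3 their mean was 0.02 (adjusted p = 0.194), and the call also ended without double-null array 2 (-0.05, 0.118), Fz1-null array 1 (-0.02, 0.491) or Fz1-null array 3 (-0.04, 0.132), among probe sets above the median value (-0.04, 0.237), with array weights (-0.02, 0.391) and with repeated quantile normalisation (-0.01, 0.404). The mean was -0.10 without double-null array 1 and -0.07 without Fz1-null array 2. Extracellular matrix genes were lower in 19 of 26 members by a mean of -0.06 (adjusted p = 0.0345; 0.695 with an estimated correlation), with Has3, a hyaluronan synthase, at -0.22 (SE 0.13), Tnc at -0.20 (SE 0.15) and Fbln5 at -0.13 (SE 0.10), and pair means of -0.08, -0.03 and -0.07. Their mean lay at 0.01 without double-null array 1 (adjusted p = 0.909) and at 0.003 without Fz1-null array 3 (0.927), and the call ended without double-null array 2 (-0.07, 0.114), among probe sets above the median value (-0.07, 0.123) and with repeated quantile normalisation (-0.04, 0.19). The mean was -0.12 without double-null array 3 or Fz1-null array 1.

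Hypoxia and glycolysis genes were higher in 19 of 25 members by a mean of 0.05 (camera adjusted p = 0.0321; 0.695 with an estimated correlation), with the vessel growth factor Vegfa at 0.11 (SE 0.08), the glycolytic enzyme Pgk1 at 0.12 (SE 0.10) and Adm at 0.14 (SE 0.09). The mean of the pair numbered 2 was 0.19, those of the pairs numbered 1 and 3 were -0.02 and -0.003, beside endothelial pair means of -0.03, 0.19 and -0.01 in the order of the numbers. Without double-null array 2 the list's mean was -0.01 (adjusted p = 0.742). The call also ended without Fz1-null array 1 (0.05, 0.0691) or Fz1-null array 2 (0.05, 0.202), and the mean was 0.10 without double-null array 1. Immediate-early genes were split 9 to 9, with a mean of -0.01, a median of 0.01 and an upward camera direction (adjusted p = 0.960), and p53 targets were lower in 15 of 18 (adjusted p = 0.179). Their members with the smallest p were Ccn1 (0.13, SE 0.08), Klf4 (-0.21, SE 0.12), Fos (-0.11, SE 0.09), Perp (-0.32, SE 0.17), Pmaip1 (-0.31, SE 0.19) and Eda2r (0.25, SE 0.13).

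Of the lists of cell types that a dissected palate can hold, the epithelial, osteogenic and skeletal muscle ones passed camera at the preset correlation. Epithelial markers fell as a group by camera, with 24 of 25 members lower, none past the threshold alone, and a mean log2 difference of -0.15 (camera adjusted p = 2.8e-06; 0.695 with an estimated correlation), with the basal keratins Krt14 at -0.37 (SE 0.16) and Krt5 at -0.35 (SE 0.18) and the splicing factor Esrp2 at -0.22 (SE 0.10). The mean was 0.01, -0.09 and -0.37 in the pairs numbered 1, 2 and 3, and over the list -0.08 without double-null array 3 (adjusted p = 0.0178) and -0.23 without Fz1-null array 1 (3.3e-13). In the pair numbered 1, 13 of 25 were lower. Osteogenic genes were lower in 11 of 12 members by a mean of -0.32 and a median of -0.19 (adjusted p = 0.00023; 0.695 with an estimated correlation), with pair means of -0.16, -0.67 and -0.12. Without Ibsp, an alternative added after its values were seen, the mean was -0.16 (adjusted p = 0.0016). Besides Ibsp, they held Alpl, an alkaline phosphatase of bone-forming cells (-0.38, SE 0.20, pair differences -0.31, -0.45 and -0.37), and Msx2, a homeobox gene (-0.32, SE 0.12). Alpl and Msx2 were the 2 members past the threshold adjusted over the list alone, and only with the replicate block (adjusted p = 0.0053 and 0.038, against 0.367 for each without it). The osteogenic call ended without double-null array 2 (mean -0.16, adjusted p = 0.112). The mean was -0.50 without double-null array 3 and -0.49 among probe sets above the median value.

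Skeletal muscle genes were higher in 27 of 28 members by a mean of 0.10 (camera adjusted p = 0.0262; 0.695 with an estimated correlation), with Myf6 at 0.16 (SE 0.13) and Cdh15 at 0.15 (SE 0.12), while the satellite cell factor Pax7 lay at -0.22 (SE 0.13). The pairs went apart, with means of -0.11, -0.19 and 0.60. Without double-null array 3 the list's mean was -0.14 and passed in the opposite direction (adjusted p = 9.0e-11), and without Fz1-null array 3 the call ended (0.09, 0.103), as it did with array weights (0.01, 0.592). The mean was 0.22 without double-null array 1 or 2. Neuronal genes had pair means of -0.27, -0.11 and 0.22 and did not pass (13 of 20 lower, adjusted p = 0.289). They passed lower without Fz1-null array 2 (-0.17, 0.0060) or double-null array 3 (-0.16, 0.00072) and higher without Fz1-null array 1 (0.09, 0.0374). Members were Prph at -0.30 (SE 0.22), Nefm at -0.24 (SE 0.30) and Nefh at -0.12 (SE 0.13), genes of neuronal intermediate filaments. Nefm lay at 0.05 without double-null array 2 and 0.03 without Fz1-null array 1, and Prph at 0.03 by the mean of all its probe sets.

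Endothelial and macrophage markers missed the threshold without the block and passed with it. Endothelial markers were higher in 13 of 17 members (adjusted p = 0.0533, and 0.0375 with the block), with the tight junction gene Cldn5 at 0.20 (SE 0.08), Tek at 0.14 (SE 0.07) and Sox17 at 0.12 (SE 0.11). Macrophage markers were higher in 12 of 15 (adjusted p = 0.0574, and 0.0185 with the block), with Tyrobp at 0.19 (SE 0.11), C1qc at 0.17 (SE 0.15) and Ptprc at -0.11 (SE 0.10). With the block and an estimated correlation the adjusted p was 0.829 for both. Both also passed among probe sets above the median value (0.00040 and 0.00038), on the log2 scale with 32 added (0.0256 and 0.0333), by the mean of all probe sets of a gene (0.0238 and 0.0135) and without double-null array 1 (0.00076 and 0.00036). Without double-null array 2 their means lay at -0.01 each. Endothelial markers passed also with array weights (0.0326), repeated quantile normalisation (0.0141) and without double-null array 3 (0.0178) or Fz1-null array 3 (0.0270), and macrophage markers without Fz1-null array 2 (0.0178).

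The remaining cell type lists did not pass camera in the main setting. Chondrogenic genes were higher in 13 of 21 (adjusted p = 0.442), with Epyc at 0.27 (SE 0.28), Comp at 0.23 (SE 0.21) and Snorc at 0.13 (SE 0.20), and Schwann and neural crest glia genes in 6 of 9 (0.635), with Erbb3 at -0.12 (SE 0.08), Cdh19 at 0.12 (SE 0.15) and Foxd3 at 0.07 (SE 0.08). Chondrogenic genes passed higher without double-null array 1 (mean 0.27, adjusted p = 2.6e-06) or Fz1-null array 3 (0.15, 0.0270), and lower without Fz1-null array 1 (-0.18, 0.0275). Without double-null array 3, Epyc lay at -0.01, Comp at -0.02 and Snorc at -0.03. Snorc lay at -0.04 without Fz1-null array 1, and Cdh19 at -0.02 without Fz1-null array 2. Erythroid genes were higher in 10 of 14 (adjusted p = 0.186), with the globin regulators Klf1 at 0.18 (SE 0.09) and Gata1 at 0.12 (SE 0.09) and Hemgn at -0.12 (SE 0.13), and passed without double-null array 3 (mean 0.11, adjusted p = 0.0017) or Fz1-null array 1 (0.08, 0.0470) and with array weights (0.08, 0.0440). Pericyte and smooth muscle genes were higher in 7 of 10 (adjusted p = 0.297), with Myh11 at 0.18 (SE 0.15), Kcnj8 at 0.11 (SE 0.08) and Pdgfrb at -0.16 (SE 0.09), and passed without double-null array 1 (0.14, 0.0290). Sensory and forebrain neuroepithelium genes were lower in 6 of 10 (adjusted p = 0.730), with Emx2 at -0.29 (SE 0.18) and Dlx2 at 0.13 (SE 0.10), and Six6 at 0.22 (SE 0.24). They passed lower without double-null array 2 (-0.16, 0.0111) and higher without double-null array 3 (0.10, 0.0178). Pituitary genes were split 3 to 3 (adjusted p = 0.272), with Six6 at 0.22 (SE 0.24), Pomc at 0.20 (SE 0.18) and Lhx3 at 0.11 (SE 0.09). Pomc lay at -0.01 without Fz1-null array 1. The list passed without Fz1-null array 2 (0.20, 0.0060) and among probe sets above the median value (0.10, 0.0374).

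In all, 10 of 28 lists passed camera with the preset correlation, 8 lower and 2 higher, and 11 passed with the replicate block, 9 of them the same lists. With an estimated correlation 0 passed (lowest adjusted p = 0.695), and by fry 0 passed in 1 direction (lowest adjusted p = 0.902) or in either (lowest 0.0914, Wnt receptors and co-receptors). With the replicate block 0 passed with an estimated correlation or by fry in 1 direction, and fry in either direction was not examined with the block. Over all probe sets, no list had a member past the threshold without the block, and Fzd2 was the 1 member past it with the block.

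**Figure D3:**
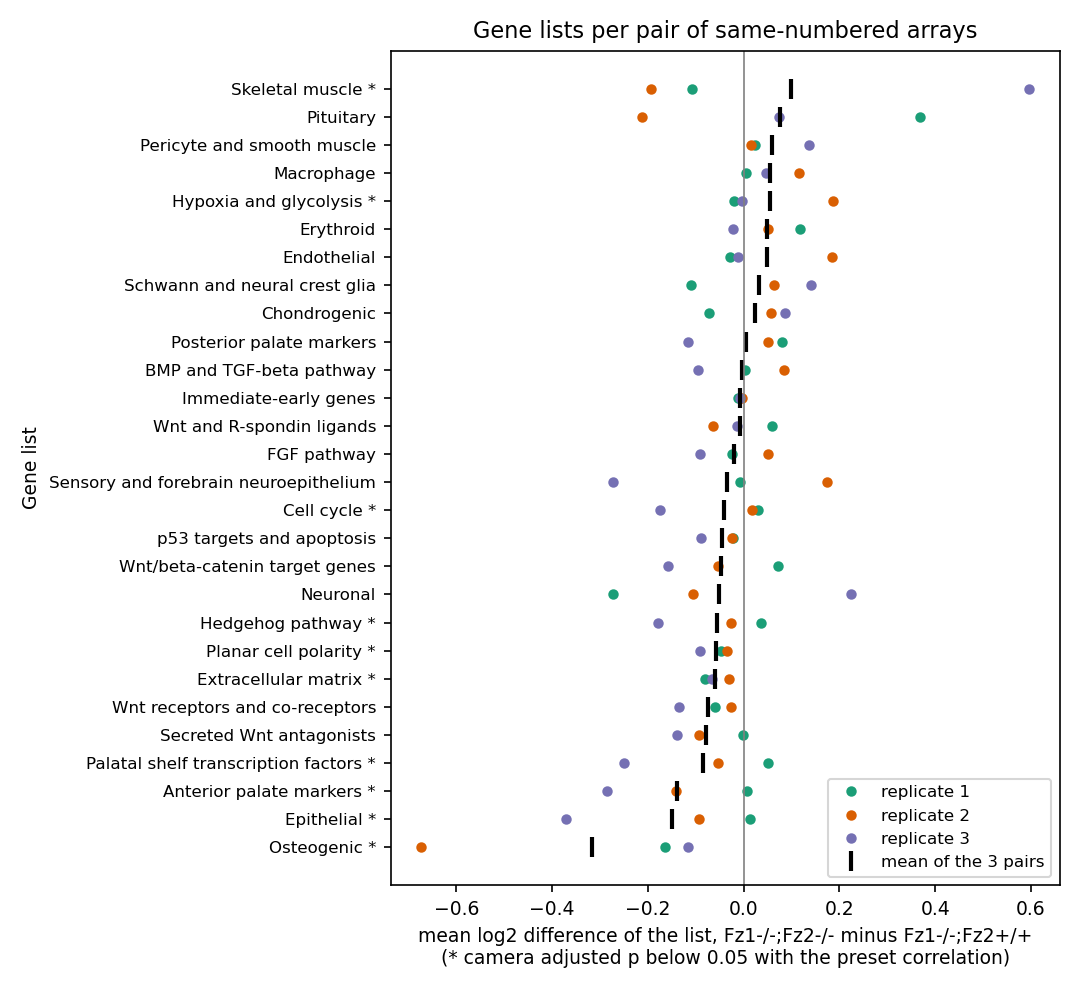
Mean log2 difference (double-null minus Fz1-null, horizontal axis) of the measured members of each gene list (vertical axis), with a coloured point for each pair of same-numbered arrays and a black tick for their mean; an asterisk marks lists with a camera adjusted p below 0.05 at the preset correlation. The pair numbered 3 lies at 0.60 for skeletal muscle and -0.37 for epithelial markers, and the pair numbered 2 at -0.67 for osteogenic genes.

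The authors' deposited table gave 814 probe sets a p-value under 0.05 (1.81% of those tested), 490 higher and 324 lower in the double-null palates. In the authors' deposited table Fzd2 had signed fold changes of 2.38, 2.57 and 2.78, positive because that table sets Fz1-null over double-null palates.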

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

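The replicate block with an estimated correlation or fry, the block with a pair of arrays left out, the deposited p-values with adjustment, the Wnt receptor list without Fzd1 and Fzd2, and the osteogenic list without Ibsp were chosen only after the data were seen. The count of 0 probe sets past limma's threshold without the block (431 at an unadjusted p under 0.05) held under all alternatives run except the replicate block, which gave 3, and 93, 3 and 3 without replicate 1, 2 and 3, and the cause of the 93 was not tested. Fzd2 lay at -1.25 with the block (adjusted p = 0.00889) and at -1.35 to -1.16 with the block and a pair of arrays left out (-1.25 without replicate 1). Without the block, its value was -1.36 to -1.19 when 1 array was left out, with adjusted p from 0.105 to 1.00. The block changed the calls of the Hedgehog, endothelial and macrophage lists given above, and no other list call.

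The count of 10 lists became 6 with array weights, 6 with quantile normalisation repeated, and 0 with an estimated correlation, 0 with fry, and 0 with the block and either of these; it was 7 to 13 without 1 array, and 8 to 14 under the other settings run. Of the 10 called lists, 4 kept their call among probe sets above the median value, where 4 others passed, 4 with array weights (2 others) and 5 with repeated quantile normalisation (1 other). Without 1 array, 4 to 9 kept it, the 4 without double-null array 3, where skeletal muscle passed in the opposite direction. Estimated correlation and fry allow for genes that move together across arrays. The cause of the 2 counts of 6 was not tested. Without 1 array, a mean log2 difference crossed 0 for cell cycle (-0.10 to 0.023), extracellular matrix (-0.12 to 0.0088), Hedgehog (-0.11 to 0.029), hypoxia and glycolysis (-0.012 to 0.10), palatal shelf transcription factors (-0.14 to 0.033) and skeletal muscle (-0.14 to 0.22). Over the 18 alternatives of each called list (19 for osteogenic), adjusted p reached 0.927 for extracellular matrix and 0.902 for each of the other 9, and fell as low as 3.3e-13 for epithelial markers. Epithelial markers kept their call without each array in turn, at -0.23 to -0.08. The robust option does not apply to camera and was not run for the lists.

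Of 1459 alternative values of 100 named probe sets, 1441 kept their direction and side of the threshold, 2 passed it (the dimmer 2 Fzd2 probe sets with the block), and 16 reversed. Without 1 array these were Bambi (-0.22 to 0.0094), Cdh19 (-0.023 to 0.28), Comp (-0.018 to 0.39), Efnb1 (-0.12 to 0.0047), Eif2s3y (-1.82 to 0.42), Epyc (-0.0084 to 0.54), the dimmer Fzd1 probe set (-0.13 to 0.027), Kdm5d (-0.30 to 0.49), Nefm (-0.46 to 0.055), Pomc (-0.013 to 0.39), Snorc (-0.043 to 0.28) and Xist (-2.34 to 0.29), none past the threshold. By the mean of all probe sets of a gene, Kdm5d lay at -0.15 and Prph at 0.032. Fewer arrays or other probe sets entered these values, and the cause was not tested further. The block, the trend and the robust option leave a difference unchanged, and apart from Fzd2 no named probe set lay near the threshold. Many of the 1441 values could therefore hardly have changed. Signals near the floor, such as the dimmer Fzd1 probe set at a log2 value near 4.4, limit what a difference can show.

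The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Probe sets past the threshold were 0 in the real split and at most 0 in the others, so all 10 gave as many. At an unadjusted p under 0.05 there were 431 and at most 5504, with 8 splits giving as many. Lists past camera were 10 and at most 14, with 4 splits giving as many. Splits that keep a same-numbered pair together gave 2736 to 5504 probe sets, which points to a structure of the sample pairs, while the 3 others that part all pairs, as the real one does, gave 224, 301 and 913. In the same order, camera called 14, 12 and 8 lists in these 3 splits, against 10 in the real one.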

Other observations

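The genes in these first paragraphs were chosen after their values were seen, and so were the tests below of epithelial markers, of the chromosome segment around Fzd2 and of the 4 Zic and Sox1 probe sets not named by p. The other tests of Zic1, Zic5 and Sox1 and of the genes within 200 kb of Fzd2 had predictions written before they were run. Their genes Zic1, Zic5, Sox1 and Gm11627 were nevertheless picked by smallest p in these same data. Double-null array 3 stood apart for Hox genes, which pattern the hindbrain and trunk. Against Fz1-null array 3, Hoxa5 was higher by a log2 difference of 2.92 (7.70 against 4.78), Hoxb5 by 2.52, Hoxb3 by 2.38, Hoxb6 by 1.84, Hoxa3 by 1.76 and Hoxc4 by 1.63, each by its most different probe set. In the same pair the other probe set of Hoxa5 differed by 0.25 and that of Hoxb3 by 1.17. Other probe sets of Hoxa3 differed by -0.002, 0.25 and 0.65. At least 2-fold higher in that pair were 9 of 48 Hox probe sets, against 0 in each of the other pairs. Of genes known from neurons or their precursors some were higher there, each by its most different probe set, Lamp5 (2.32), Neurod6 (2.22), Skor1 (1.85), Lhx1 (1.83, and 0.49 and 0.20 in the pairs numbered 1 and 2), Slc1a2 (1.65, and 0.17 and 0.32) and Gad1 (1.42, and 0.78 and 0.20), and others lower, Nr2e1 (-0.52), Olig1 (-0.41) and Dmrta2 (-0.41), and the sensory and forebrain neuroepithelium list had a mean of -0.27 with 9 of 10 lower. The chemokine Cxcl14 was lower there (-1.77), with 0.40 and -1.05 in the pairs numbered 1 and 2. These are single pairs of arrays, with no test.

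Double-null array 2 was higher than Fz1-null array 2 for the germ cell genes Ddx4 (2.37, and 0.02 and 0.05 in the pairs numbered 1 and 3) and Slc25a31 (2.35, and 0.24 and -0.19). Sex-linked genes differed between arrays whose labels give mixed gender, each given by its most different probe set. Xist read 4.58 on double-null array 2, against 12.24 on Fz1-null array 2 and 10.50 or more on every other array. The Y-linked Eif2s3y, Uty and Kdm5d were higher on double-null array 2 than on Fz1-null array 2, by 2.06, 2.02 and 1.96. On double-null array 1 the same Y-linked genes were lower than on Fz1-null array 1 (-3.64, -3.88 and -3.22), and in the pair numbered 3 they differed by -0.38, -0.05 and -0.57. The bone gene Ibsp read 8.02, 8.88 and 9.53 on Fz1-null arrays 1 to 3 and 6.82, 4.43 and 9.16 on double-null arrays 1 to 3.

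Zic1, Zic5 and Sox1 had 7 probe sets with a median log2 difference of 0.57, and 7 of 7 were higher in all 3 pairs. Carry-over of neural tissue would raise neural genes, and a median of at least 0.29, set from the pattern's own median, was to mark it. That mark rests on genes named by smallest p, and genes already bright in palate would rise less, so it cannot decide carry-over. Of 30 neural genes listed, 20 outside the pattern with a mean log2 value of at least 6 were used. Both Sox1 probe sets would miss that cut (5.86 and 5.79). The 20 genes had a median of 0.10 (95% interval -0.06 to 0.15), below the mark. That interval came from resampling the genes, not the arrays, so it does not measure the spread between samples. Of these 12 were higher, and 5 in all 3 pairs, Nkx6-1 (0.24), Rfx4 (0.19) and Dbx1 (0.17) among them. Outside the list, Gad1 (0.80) and Lhx1 (0.84) were also higher in all 3 pairs, each by its most different probe set. Their other probe sets, higher in all 3 pairs too, differed by 0.15 and 0.39. The Gad1 probe set at 0.80 read 4.31 to 4.49 in Fz1-null palates, near the floor. Fabp7, whose probe set was the brightest (11.35), lay at 0.14, Zic2 at 0.37 and Zic4 at 0.20, though levels of different probe sets cannot be compared. Whether 1 array carries the pattern was not decided: the lowest median without 1 array was 0.47, and 0.50 for the 4 probe sets not named by p, but naming genes by smallest p leaves little room for a fall to the bound set, and the 4 measure the same genes. Carry-over of neural tissue stays open, also from a part of the neural tube rich in these factors, which was not tested. The genotype may be a source as well, so the pattern stays a hypothesis.

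Epithelial markers were lower by a mean log2 difference of -0.15. Whether 1 array carries this cannot be told apart: without double-null array 3 the mean was -0.077 (SE over markers 0.017), close to the -0.075 that marks 0.5 of its size. A smaller share of epithelium in double-null array 3 may account for part of it, since 100% of the 25 markers were lower in the pair numbered 3 (median -0.32, SD over markers 0.24), against 13 and 15 in the pairs numbered 1 and 2. An effect of the genotype on epithelium stays open and was not tested.

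Gm11627, which neighbours Fzd2 in the RefSeq annotation of GRCm38.p6, was lower by a log2 difference of -0.54. A flanking segment of another strain, carried with the targeted allele, could change many nearby genes. The share of 1261 probe sets within 20 Mb at an unadjusted blocked p under 0.05 was 0.969 times that on other chromosomes. The 95% interval was 0.728 to 1.26, and takes probe sets as independent, though they share genes and arrays. This argues against a segment that changes many genes over the whole 20 Mb. It cannot decide on a shorter segment, which the window would dilute, or on one that changes Gm11627 alone. Of the other 10 genes within 200 kb, 2 were lower in all 3 pairs, and the lowest log2 difference was -0.18. Near the floor, 2810433D01Rik (3.74 in Fz1-null and 3.71 in double-null palates) and Meioc (3.48 and 3.37) could hardly show a fall. The brighter genes argue against a change of the whole locus as large as that of Gm11627. A smaller shared shift stays open, since 9 of the 10 had a lower mean (median -0.07). An effect of the targeted allele on Gm11627 alone stays open and was not tested.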
